A study of Caenorhabditis elegans with 12 samples.

How the data were processed

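Total RNA was sequenced from early Caenorhabditis elegans embryos of 4 strains, the N2 wild type, met-2(n4256), a lin-65 deletion and the lin-65 met-2 double mutant, with 3 libraries per strain that the labels describe as independent biological replicates. Per the labels' protocols, worms were grown at 20 °C for 60 to 65 h depending on the strain after synchronization, the embryos held between 1 and 300 cells, and libraries were made from 5 µg of RNA after removal of ribosomal RNA. The sample labels name the molecule as genomic DNA although the design and the library kit are for RNA, and the values were treated as RNA measurements. No sequencing batch is given in the labels.

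Per the submitters' processing notes, edgeR and the genome build ce10 were used. The aligner, the counting, the annotation, the library scaling and the rule that selected the genes are not given in the sources used here. The authors deposited 3 tables, 1 per mutant, and each holds log2 values for 9 mutant libraries over genes selected in that mutant. No header names the baseline of these log2 values. It was read from the values themselves as the N2 wild type, because lin-65 stood far below 0 in libraries of both strains that lack lin-65 and near 0 in met-2 libraries, and met-2 behaved in the mirrored way. A gene present in several tables had identical values in each. Together the tables held 2949 genes. Every gene in a table had a mean over its mutant's 3 libraries of at least 1 log2 unit in absolute size, which is 2-fold, with both signs present although the tables are named for genes that are up. A further criterion must have been applied, since 92 genes with a mean of at least 1 in met-2, 216 in lin-65 and 22 in the double mutant were held only by another mutant's table.

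The 3 N2 libraries have no column, and the tables hold no counts, no p-values and no expression level. Sequencing depth is therefore unknown and no interval that needs it is given. The spread of N2 is not in the values, so no test against N2 was made on single genes, and the numbers of listed genes are described as the authors' selection. Values are means over 3 libraries with the sample standard deviation (SD), which covers the mutant libraries alone. The wild-type level of listed genes is not reported for the same reason. Because the tables hold selected genes, all medians over listed genes are shifted away from 0 by the selection. Setting such a library median to 0 removes any general difference between mutants, whether from scaling or from a larger effect.

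Differences between mutants do not depend on the N2 baseline. They were tested with limma 3.58.1 in R 4.3.3 on the log2 values of the 2949 genes, with all 9 libraries in 1 fit, no covariate and Benjamini-Hochberg adjustment at 0.05. The design written in advance reserved limma contrasts for tables of all genes. They were used here because log2 values allow no count model, and their counts describe selected genes, not the genome. In simulated data for the double mutant against met-2 with 200 of the 2949 genes changed, the fit recovered 82% of changes of 1 log2 unit and 18% of changes of 0.5, with 4 false calls. The simulation drew independent noise with 1 SD per gene for all mutants. In the data the median SD of listed genes was 0.326 in met-2 and 0.115 in the double mutant, and replicate 1 of met-2 stood above the others. These figures therefore need not hold for the real contrast.

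Gene positions, names and types came from the Ensembl 115 annotation of WBcel235 by gene identifier. The authors' build was ce10, the tables hold no coordinates, no coordinate was converted and none is printed. Of the listed genes 2869 matched and 80 did not. Of those matched, 2828 were protein-coding. Where 2 identifiers share a symbol or near-identical sequence, as in the hsp-16 genes, F44E5.4 and F44E5.5, reads may have been divided between copies and single values are uncertain.

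Before the data were examined, 27 gene lists were fixed from gene symbols. They cover heterochromatin factors, germ granule and germ cell genes, meiosis, sperm, oocyte and eggshell, the first zygotic genes, body wall muscle, intestine, epidermis, neurons, pharynx, collagens, F-box proteins, MATH and BTB proteins, SKR proteins and cullins, C-type lectins, immune effectors, pals genes, heat shock genes, detoxification enzymes, chemoreceptors, nuclear hormone receptors, homeobox factors, histones, Argonaute and RNA interference factors, ribosomal proteins, and apoptosis and DNA damage genes. A further list of unnamed loci was not tested. The number of list members among listed genes was tested with a 2-sided Fisher exact test against 19985 annotated protein-coding genes, adjusted over the lists of each mutant and direction. The genes the authors tested are not known, and a background of annotated genes includes genes silent in embryos. In 100 simulations the Fisher test found a planted list in 100% and called 0.154% of unplanted ones. Most members of the planted list were placed among the selected genes, so finding it was close to assured. Members of the other lists were drawn independently. Real lists hold genes that vary together, so these figures need not hold for them. Between mutants the lists with at least 3 members were tested with camera (preset correlation, and estimated correlation) and fry of limma, adjusted over lists. Arms are the outermost parts of each autosome, the chromosome being divided by length into 3 equal parts, and positions are those of WBcel235. Shares carry Clopper-Pearson 95% intervals. Other calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

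Genes named in the text followed a rule set in advance. It took the 10 largest log2 values per mutant, up to 3 members per list, the 10 genes with the largest smallest value over the 3 mutants, and the 5 largest of each mutant's own genes, always with met-2 and lin-65. Its parts based on adjusted p and on expression level could not be applied. Genes with negative values, except met-2 and lin-65, and some further family members were named after their values were seen. Alternatives fixed in advance were a 4-fold limit, another background, other arm limits, counting neighbours within 20 kb once, leaving out each mutant library and the replicate number as a block for the double mutant against each single mutant. Centring each library on its median (also for differences over shared genes), library weights, fits of the 2 mutants compared, single libraries left out of the limma fits, the block for lin-65 against met-2, an estimated correlation of list members, neighbours counted once for shared and single lists (adjusted over the 7 parts), a limit met in every library, a background of listed genes, Spearman correlation and met-2 without replicate 1 for overlaps, lists and arms were chosen after seeing the data.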

Results

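MET-2, the worm counterpart of the histone methyltransferase SETDB1, deposits dimethylation on lysine 9 of histone H3, and LIN-65 is its cofactor. The series asked how embryonic transcripts differ from wild type when either protein or both are missing. Values were available for 9 mutant libraries, 3 each of met-2, lin-65 and the lin-65 met-2 double mutant, as log2 ratios to N2 for 2949 genes selected by the authors. N2 was inferred as the baseline, and how its 3 libraries entered is not given. Libraries of 1 mutant correlated with Pearson's r of 0.882 to 0.967 across genes, and libraries of different mutants with 0.538 to 0.854 (genes are not independent replicates). The first principal component held 69.2% of the variance and the second 18.8%. Replicate 1 of met-2 stood apart, with a median over all listed genes of 1.53 against 1.06 and 1.08 in replicates 2 and 3. The double mutant libraries had medians of 1.47, 1.48 and 1.49, and the lin-65 libraries 0.78, 0.97 and 0.77.

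The mutated genes themselves matched the strain labels. The lin-65 transcript (WBGene00022149, chromosome I) stood at −5.88 ± 0.09 (SD, n = 3) in lin-65 and −6.04 ± 0.21 in the double mutant, against −0.22 ± 0.04 in met-2. The met-2 transcript (WBGene00019883, chromosome III) stood at −2.36 ± 0.04 in met-2 and −2.76 ± 0.06 in the double mutant, against −0.02 ± 0.08 in lin-65. Of the 20 heterochromatin factors in the fixed list, met-2 and lin-65 were the only members listed in any mutant, and no member was listed higher. All following values after a ± sign are SDs over 3 libraries.

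Embryos lacking MET-2 had higher transcripts of differentiated tissues, led by body wall muscle. Of 22 muscle genes 19 were listed higher, against 2.04 expected from the annotation (Fisher exact test, adjusted p = 3.46e-16), with a median of 1.73. They included the thick filament protein unc-15 at 2.22 ± 0.34, the myosin heavy chain unc-54 at 2.09 ± 0.37 and tropomyosin lev-11 at 2.06 ± 0.28. Neuronal genes followed with 15 of 30 (adjusted p = 8.29e-08), among them the synaptic vesicle priming factor unc-13 at 2.36 ± 0.45 and the neuropeptide-processing enzyme egl-21 at 1.94 ± 0.58. Intestinal genes were listed for 11 of 29 (adjusted p = 1.36e-04), with the aspartyl proteases asp-1 at 2.37 ± 0.43 and asp-6 at 2.26 ± 0.43. Pharyngeal genes reached 5 of 10 (Fisher exact test, adjusted p = 0.00395), including troponin C tnc-2 at 2.51 ± 0.22 and the pharyngeal myosins myo-1 at 2.25 ± 0.52 and myo-2 at 2.20 ± 0.52. Cuticle collagens gave 52 of 173 (adjusted p = 6.83e-14), with col-45 at 2.67 ± 0.18 and col-144 at 2.50 ± 0.46. For epidermal genes other than collagens, 5 of 19 were listed, which did not pass (Fisher exact test, adjusted p = 0.071); qua-1, a hedgehog-related protein, stood at 2.36 ± 0.35 and the transcription factor grh-1 at 2.28 ± 0.29. At a 4-fold limit 1 neuronal gene was left and that list no longer passed (Fisher exact test, adjusted p = 0.694), while the other lists that passed still did. Against only the protein-coding genes listed in at least 1 mutant, muscle still passed (Fisher exact test, adjusted p = 0.00546). Collagens (adjusted p = 0.0849), intestinal (0.433), neuronal (0.528) and pharyngeal genes (0.824) did not. Of these 2828 background genes 1853 were themselves listed higher in met-2, which leaves less room for over-representation. Medians of these tissue lists were highest in replicate 1 of met-2, with muscle genes at 2.14 against 1.53 and 1.57, and pharyngeal genes at 2.71 against 1.72 and 2.04.

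Chemoreceptors and F-box genes were listed less often in met-2 than the annotation gives. The annotation includes genes without transcripts in embryos, and only 31 chemoreceptors and 28 F-box genes had values in any mutant. Under-representation among expressed genes was therefore not measured. Chemoreceptors were listed for 11 of 1248 genes against 116 expected (adjusted p = 1.33e-37) and F-box proteins for 10 of 322 against 29.9 (adjusted p = 1.33e-04). No histone gene of 72 (adjusted p = 0.00498) and no ribosomal protein gene of 78 (adjusted p = 0.00395) was listed higher. None of the 20 oocyte and eggshell genes and none of the 24 meiosis genes was listed higher in met-2. The highest single values were those of the chemoreceptor srw-85 at 4.54 ± 0.16, C55C3.3 at 4.11 ± 0.13 and ZK1053.2 at 3.25 ± 0.08, and C42D4.3 stood at 2.90 ± 0.39. C42D4.3 stood at −0.83 in lin-65, a limma difference from met-2 of −3.73 (SE 0.21, adjusted p = 7.43e-10). In all, 1922 genes were listed higher in met-2, with a median of 1.45, and 19 lower. A limit of 4-fold left 286 of the higher genes, and the numbers rest on the authors' selection, with no test against N2 possible here.

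Embryos lacking LIN-65 had fewer listed genes and a different leading group, transcripts of the oocyte and eggshell. Of 20 such genes 8 were listed higher (0.824 expected, Fisher exact test, adjusted p = 8.75e-06), with a median of 1.52. The eggshell chondroitin proteoglycans cpg-1 and cpg-2 stood at 2.02 ± 0.15 and 1.79 ± 0.21, the eggshell protein cbd-1 at 1.74 ± 0.13, the yolk receptor rme-2 at 1.66 ± 0.20 and the oocyte maturation factor oma-2 at 1.39 ± 0.08. Meiosis genes were listed for 4 of 24, which did not pass (adjusted p = 0.106); him-3 and syp-2, both parts of meiotic chromosome axes or the synaptonemal complex, stood at 1.19 ± 0.11 and 1.15 ± 0.15. Germ granule and germ cell genes gave 3 of 31 (adjusted p = 0.361), namely wago-4 at 1.70 ± 0.09, pgl-3 at 1.44 ± 0.12 and car-1 at 1.27 ± 0.15. Body wall muscle genes were also over-represented, with 7 of 22 (adjusted p = 1.75e-04) and a median of 1.21. No intestinal or pharyngeal gene was listed higher, and 1 neuronal gene was, ida-1 at 1.19 ± 0.08. This rests on the authors' further criterion, since unlisted members passed 2-fold as well, with means of 1.68 for tnc-2, 1.52 for unc-13 and 1.04 for asp-1, and all intestinal, pharyngeal and neuronal genes with values lay above 0 in every lin-65 library. Against the annotation, which includes genes silent in embryos, chemoreceptors were under-represented, with 11 of 1248 (51.4 expected, Fisher exact test, adjusted p = 8.78e-11). With a 4-fold limit no list was over-represented, and against only the protein-coding genes listed in at least 1 mutant the oocyte list passed (Fisher exact test, adjusted p = 0.00133) and the muscle list did not (adjusted p = 0.987). The highest values in lin-65 were C55C3.3 at 3.91 ± 0.04, Y37E11AL.1 at 3.52 ± 0.13, the chemoreceptor sri-62 at 3.51 ± 0.11, mihp-1 at 3.31 ± 0.02 and the cyclic nucleotide phosphodiesterase pde-1 at 3.06 ± 0.13.

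Inducible heat shock genes were the group with the lowest values in lin-65. Of 16 heat shock genes 9 were listed lower (0.0809 expected, Fisher exact test, adjusted p = 4.48e-16), with a median of −2.60. These 9 identifiers repeat the symbols hsp-16.1 and hsp-16.48 and hold the near-identical F44E5.4 and F44E5.5. They are fewer distinct genes, and the Fisher test treats them as independent. Counting neighbours once was not run for lower genes. The chaperone hsp-70 stood at −4.69 ± 0.37 and the small heat shock protein hsp-16.2 at −3.06 ± 0.43; hsp-16.41 stood at −2.53 ± 0.46. In the double mutant the same 3 genes stood at −4.79 ± 0.15, −3.52 ± 0.17 and −2.97 ± 0.08. In met-2 they stood at −0.94 ± 0.26, −0.37 ± 0.23 and −0.32 ± 0.19, and none was listed. Over the 9 genes the median difference of lin-65 from met-2 was −2.34, and each of the 9 passed limma's test, with hsp-70 at −3.75 (SE 0.21, adjusted p = 7.43e-10). Other members of the list went the opposite way in lin-65. The small heat shock genes hsp-43, hsp-12.2 and hsp-12.1 stood at 1.95 ± 0.32, 1.32 ± 0.22 and 1.30 ± 0.22, and hsp-12.2 is also a member of the muscle list. In all, 854 genes were listed higher in lin-65, with a median of 1.30, out of 973 in its table. At least 4-fold were 48 of the higher and 17 of the lower genes.

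**Figure D1:**
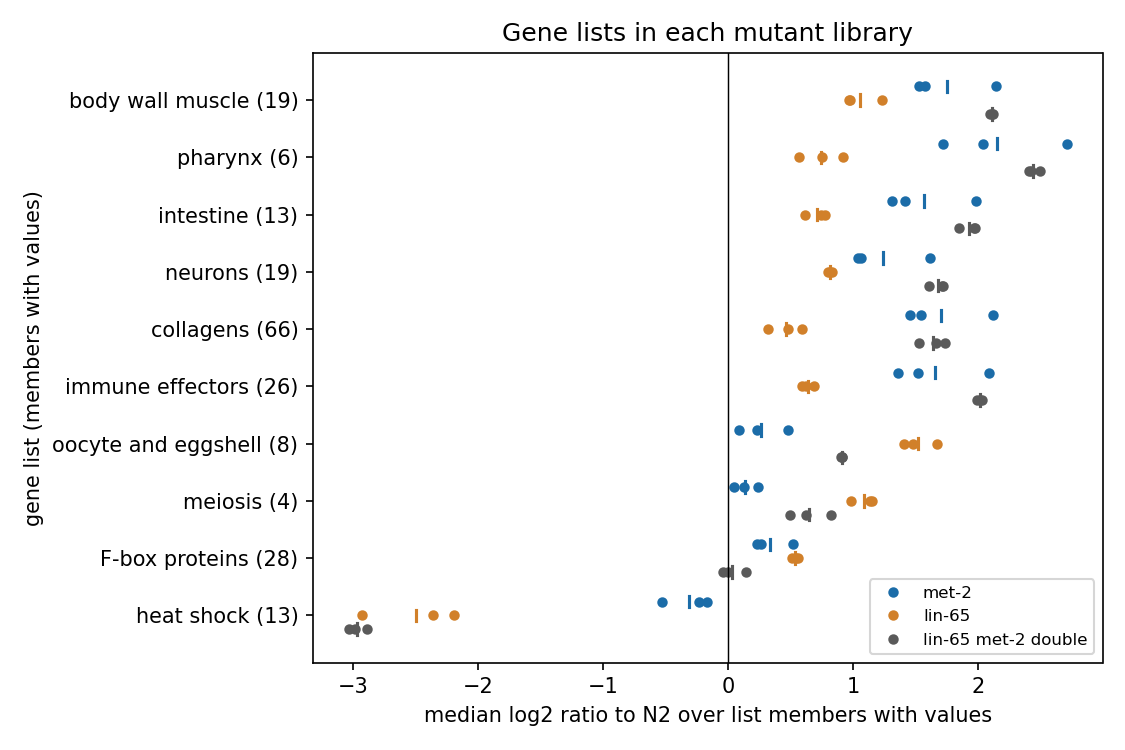
Median log2 ratio to N2 (horizontal axis) of the members with values in 10 gene lists (vertical axis, number of members in brackets) for each of 9 libraries (points) with the mean of 3 libraries (vertical ticks), members having values only if the authors listed them in at least 1 mutant. Muscle genes lie at 1.53 to 2.14 in met-2 libraries, oocyte and eggshell genes at 1.41 to 1.67 in lin-65 libraries, and heat shock genes below −2 in lin-65 and the double mutant.

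The double mutant combined tissue genes as in met-2 with low heat shock genes as in lin-65. Muscle genes were listed higher for 19 of 22 (Fisher exact test, adjusted p = 5.23e-14, median 2.05), with unc-15 at 2.68 ± 0.05 and lev-11 at 2.45 ± 0.07. Neuronal genes gave 19 of 30 (adjusted p = 3.52e-10), with unc-13 at 2.84 ± 0.05. Intestinal genes gave 13 of 29 (adjusted p = 5.45e-05), with asp-1 at 2.84 ± 0.11, and pharyngeal genes 6 of 10 (Fisher exact test, adjusted p = 0.00128), with tnc-2 at 2.88 ± 0.14. Collagens gave 60 of 173 (adjusted p = 7.81e-14), with col-165 at 2.97 ± 0.09. Immune effectors passed in this mutant, with 26 of 131 (adjusted p = 0.025), among them fipr-21 at 3.02 ± 0.16, the saposin-like spp-13 at 2.79 ± 0.12 and lysozyme lys-1 at 2.58 ± 0.11. With members within 20 kb counted once this list no longer passed (20 genes, adjusted p = 0.379). Against only the protein-coding genes listed in at least 1 mutant, none of these 6 lists passed (Fisher exact test, adjusted p from 0.142 to 0.856). This background could hardly be exceeded, since 2422 of its 2828 genes were themselves listed higher in the double mutant. Every muscle, neuronal, intestinal, pharyngeal and immune effector gene with values was listed, and 60 of 66 collagens were. The lost calls therefore do not show a lost over-representation. The corresponding counts of immune effectors were 19 in met-2 (adjusted p = 0.118) and 4 in lin-65. Oocyte and eggshell genes were listed for 3 of 20 (Fisher exact test, adjusted p = 0.822), with cpg-1 at 1.48 ± 0.06. Heat shock genes were listed lower for 9 of 16 (Fisher exact test, adjusted p = 1.38e-15, median −3.32), again with near-identical copies among the 9. F-box genes, substrate adaptors of ubiquitin ligases, were listed lower for 12 of 322 (1.84 expected, adjusted p = 4.28e-06), with fbxb-97 at −1.41 ± 0.12 and fbxa-47 at −1.32 ± 0.14, while 9 were listed higher, fewer than the 39.0 expected (adjusted p = 1.36e-08).

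Over all genes of the double mutant, 2508 were listed higher, with a median of 1.58, and 130 lower; 639 of the higher genes exceeded 4-fold. The highest values belonged to sri-62 at 3.60 ± 0.08, Y37E11AL.1 at 3.58 ± 0.14, ZK1025.3 at 3.49 ± 0.11, mihp-1 at 3.48 ± 0.09 and the ground-like gene grl-7 at 3.40 ± 0.03. The SD of a listed gene had a median of 0.115 in the double mutant, 0.174 in lin-65 and 0.326 in met-2, and replicate 1 of met-2 stood apart from the others. As in met-2, chemoreceptors (13 of 1248, Fisher exact test, adjusted p = 7.75e-52), histone genes (0 of 72, adjusted p = 5.88e-04) and ribosomal protein genes (0 of 78, adjusted p = 2.85e-04) were under-represented. So were sperm genes (3 of 89, adjusted p = 0.0221), with 4 listed in met-2 (adjusted p = 0.295) and 1 in lin-65 (adjusted p = 0.57). This background too includes genes without transcripts in embryos.

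The following lists did not pass in the higher direction in any of the 3 mutants. In met-2, lin-65 and the double mutant, C-type lectins were listed higher for 24, 7 and 29 of 240 genes, nuclear hormone receptors for 21, 13 and 43 of 269, detoxification enzymes for 21, 4 and 32 of 232, and MATH or BTB proteins for 10, 8 and 12 of 90. Homeobox factors gave 8, 5 and 14 of 82, Argonaute and RNA interference factors 2, 2 and 3 of 33, and pals genes 2, 0 and 3 of 38. SKR proteins and cullins were listed higher in the double mutant alone, for 2 of 26, skr-3 at 1.16 ± 0.11 and cul-6 at 1.11 ± 0.01. None of the 20 first zygotic genes and none of the 17 apoptosis and DNA damage genes was listed higher. Examples with larger values in the double mutant were clec-180 at 2.74 ± 0.05, nhr-170 at 2.34 ± 0.06 and cyp-32B1 at 2.16 ± 0.07. Another, lim-9 at 2.51 ± 0.06, was counted in the homeobox list by its symbol alone.

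To ask how far the mutants shared genes, the lists were intersected. Genes listed higher in all 3 mutants numbered 658, and a further 1125 were shared by met-2 and the double mutant without lin-65. Of the 1922 met-2 genes 92.8% were listed higher in the double mutant, and of the 854 lin-65 genes 84.5% were. The met-2 and lin-65 lists shared 674 genes, which were 78.9% of the lin-65 list and 35.1% of the met-2 list. Among protein-coding genes these overlaps were 7.66, 6.99 and 8.49 times those of independent lists drawn from the annotation, 225, 99.7 and 76.3 genes, and the 1-sided Fisher exact p was too small for the software to represent. Against only the protein-coding genes listed in at least 1 mutant, a background chosen after seeing the data, the ratios were smaller. They were 1.20 for met-2 with lin-65 and 1.08 for met-2 with the double mutant. For lin-65 with the double mutant the ratio was 0.989 (1-sided Fisher exact test, p = 0.838). Of these 2828 genes 2422 were listed higher in the double mutant, so ratios with that list could not lie far above 1. Among genes listed higher in all 3 mutants, those with the largest smallest value included C55C3.3, mihp-1, pde-1, the cuticlin gene cut-6 at 2.63, 2.23 and 3.24 in met-2, lin-65 and the double mutant, and acd-2 at 2.70, 2.50 and 2.97.

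**Figure D2:**
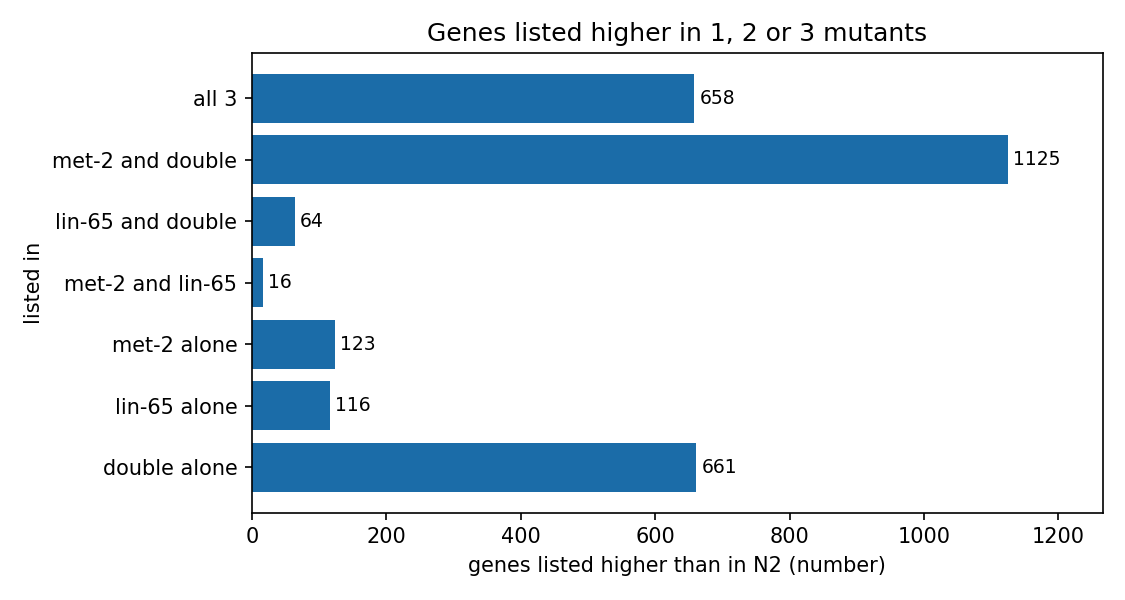
Number of genes listed higher than N2 (horizontal axis) in all 3 mutants, in 2 of them or in 1 alone (vertical axis). The largest class is the 1125 genes shared by met-2 and the double mutant.

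Genes listed in met-2 mostly had positive values in the other mutants as well. Of the met-2 genes 97.1% had a positive mean in lin-65, with a median of 0.94, and 99.9% in the double mutant. A shared N2 baseline and the selection favour like signs, and these shares were not simulated for unchanged mutants. Genes listed in met-2 alone numbered 123 and were led by srw-85 and by ZK1053.1 at 2.66 ± 0.07 and the cyclin cya-2 at 2.09 ± 0.13. Those in lin-65 alone numbered 116 and were led by C27C7.1 at 2.41 ± 0.13, fbxa-107 at 1.70 ± 0.20 and snpc-1.3 at 1.68 ± 0.17. Those in the double mutant alone numbered 661, with moa-1 at 2.49 ± 0.04 and cex-1 at 2.43 ± 0.13. For cex-1 the met-2 mean was 1.95, so membership of 1 list did not follow from the size of the value alone. Among lower genes, lin-65 and the double mutant shared 67 (p = 3.81e-107, 1-sided Fisher exact test) and met-2 shared 5 with lin-65 and 11 with the double mutant.

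All 3 lists were taken as set against the same N2 libraries, which would make them alike by chance. In 100 simulations of unchanged mutants, with N2 assumed to vary as the mutants do, the across-gene Pearson correlation was 0.497 for met-2 with lin-65, 0.499 for met-2 with the double mutant and 0.50 for lin-65 with the double mutant, against 0.660, 0.865 and 0.798 observed. The covariances observed were 0.315, 0.529 and 0.511, against 0.0226, 0.0226 and 0.0227 simulated, and at most 2 genes were shared in the simulations. The observed values come from genes selected for large values in at least 1 mutant, and no such selection was simulated. The simulations therefore cannot tell how far the observed values exceed those of unchanged mutants. The N2 libraries could not be divided between the comparisons, so their part in the observed overlap was not measured.

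Over shared genes the double mutant stood higher than either single mutant on the deposited scale, and library scaling could not be separated from a larger effect. The median difference from met-2 was 0.32 over 1783 shared genes, 88.8% of which were higher in the double mutant, but single library pairs gave medians from −0.04 to 0.52, and without replicate 1 of met-2 the median was 0.51. The median difference from lin-65 was 0.66 over 722 genes, with library pairs between 0.48 and 0.77. The median difference of lin-65 from met-2 was −0.30 over 674 genes (library pairs −0.72 to 0.04), and −0.14 without replicate 1 of met-2. With library medians set to 0 the differences were 0.07, 0.01 and 0.09 in the same order, with 61.4%, 52.5% and 63.65% of the genes above 0. These medians were taken over the listed genes, so centring removes a true general difference as well. The smaller values therefore do not show that scaling was the cause. On the deposited scale, of the 658 genes listed in all 3 mutants, 575 had a higher mean in the double mutant than in both single mutants.

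Tested directly against each other, with values only for genes the authors selected, lin-65 had higher oocyte genes and lower tissue and heat shock genes than met-2. The 8 oocyte and eggshell genes with values had all been listed higher in lin-65, 0 of them in met-2 and 3 in the double mutant, so the selection favours a difference in this direction. All 8 were higher in lin-65 (limma, adjusted over all genes and also adjusted over the list alone), with a median difference of 1.17, as for cpg-1 at 1.49 (SE 0.17, adjusted p = 3.78e-06). The list's camera test passed (adjusted p = 4.16e-18) and was lost with estimated correlation (adjusted p = 0.117 with an estimated correlation). Of 4 meiosis genes, all listed in lin-65, 3 were higher (3 adjusted over the list alone; median 0.97; adjusted p = 2.14e-06, and adjusted p = 0.117 with an estimated correlation). Of 13 heat shock genes with values 12 were lower (12 adjusted over the list alone; median −2.21; adjusted p = 5.97e-07, and adjusted p = 0.359 with an estimated correlation). Collagens were lower for 50 of 66 (51 adjusted over the list alone; median −1.07; adjusted p = 2.53e-09, and adjusted p = 0.655 with an estimated correlation), as was body wall muscle for 17 of 19 (17 adjusted over the list alone; median −0.71; adjusted p = 0.0127, and adjusted p = 0.703 with an estimated correlation), with unc-54 at −1.22 (SE 0.23, adjusted p = 4.61e-04). Intestinal genes were lower for 12 of 13 and pharyngeal genes for 5 of 6, with the same counts adjusted over the list alone. Neuronal genes were lower for 12 of 19 (13 adjusted over the list alone, median −0.66). Epidermal genes other than collagens were lower for 3 of 5 (4 adjusted over the list alone, median −0.51). Neither list passed with camera (adjusted p = 0.291 and 0.554). Both passed with fry, which tests a list against no difference and not against the other listed genes (adjusted p = 0.023 and 0.0197). The selection favours these directions too, since for example 52 of the 66 collagens had been listed higher in met-2 and 6 in lin-65. No camera call of this contrast held with an estimated correlation. The oocyte, heat shock, collagen and muscle lists passed with fry in the same directions (adjusted p = 2.73e-04, 2.73e-04, 0.0012 and 0.0074). Because the median over all listed genes was −0.42, fry can also pass for lists that share this general shift. Embryo age was not separated from genotype in this contrast.

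Of the 2949 genes, 145 were higher and 1236 lower in lin-65 than in met-2 by limma. The median difference over all genes was −0.42, and with each library's median set to 0 the calls became 366 higher and 523 lower. Under that centring the oocyte list remained above (median 1.55) and the collagen, muscle and heat shock lists below (−0.68, −0.33 and −1.83). Without replicate 1 of lin-65 the lower genes numbered 780.

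**Figure D3:**
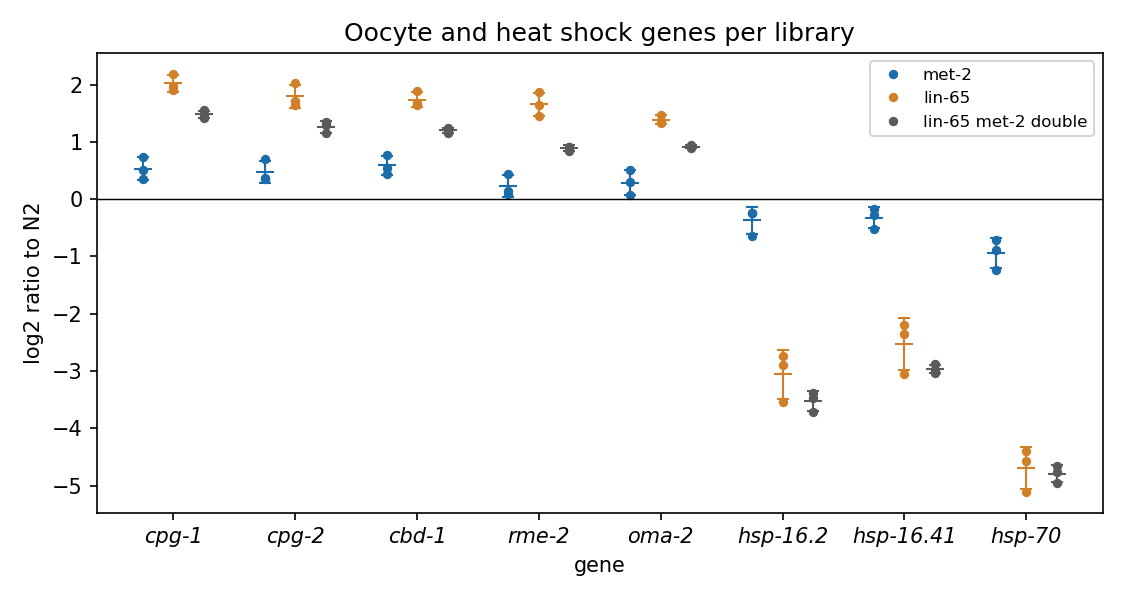
Log2 ratio to N2 (vertical axis) of 5 oocyte or eggshell genes and 3 heat shock genes (horizontal axis) in 3 libraries per mutant (points), with the mean (horizontal tick) and SD (bars). For hsp-70 the lin-65 and double mutant means are −4.69 and −4.79 against −0.94 in met-2, and for cpg-1 the lin-65 mean is 2.02 against 0.53 in met-2.

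More genes passed between the double mutant and lin-65 than between the double mutant and met-2. Against lin-65, 2190 genes were higher and 136 lower by limma, with a median difference of 0.70. All 19 muscle genes with values were higher (19 adjusted over the list alone; median 1.10; camera adjusted p = 0.00142, and adjusted p = 0.571 with an estimated correlation), as were all 13 intestinal and all 6 pharyngeal genes, with myo-2 at 1.76 (SE 0.23, adjusted p = 1.75e-05). The 8 oocyte and eggshell genes, all of them selected as higher in lin-65, were lower (8 adjusted over the list alone; median −0.54; camera adjusted p = 3.24e-13, and adjusted p = 0.131 with an estimated correlation), as was rme-2 at −0.77 (SE 0.18, adjusted p = 0.00127). With fry the muscle and oocyte lists passed in the same directions (adjusted p = 0.0022 and 0.0031). With library medians set to 0 the calls were 637 higher and 486 lower.

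Against met-2, 348 genes were higher and 145 lower in the double mutant, with a median difference of 0.32. The lower genes included 9 of 13 heat shock genes (9 adjusted over the list alone; median −2.48; camera adjusted p = 4.35e-21, and adjusted p = 0.131 with an estimated correlation) and 9 of 28 F-box genes (10 adjusted over the list alone; median −0.21). For F-box genes camera gave adjusted p = 3.47e-09, and adjusted p = 0.0208 with an estimated correlation. With fry both lists passed as lower (adjusted p = 0.0013 for heat shock and 0.0034 for F-box genes). Of these 28 genes 12 had been listed lower in the double mutant and 1 in met-2, and of the heat shock genes 9 and 0, so the selection favours lower values in the double mutant in both lists. Against lin-65 camera placed F-box genes below the other listed genes (adjusted p = 0.00998 with an estimated correlation), while their own median difference was −0.06, with 5 higher and 8 lower (4 and 6 adjusted over the list alone), and fry did not pass (adjusted p = 0.0592). Of 8 oocyte and eggshell genes 7 were higher (7 adjusted over the list alone; camera adjusted p = 0.00848, and adjusted p = 0.933 with an estimated correlation), and 1 was with library medians set to 0. Collagens had a median of 0.11 while camera placed them below the other listed genes (adjusted p = 0.0378, and adjusted p = 0.934 with an estimated correlation). With all libraries in the fit, no muscle, intestinal, neuronal or pharyngeal gene passed in this contrast. These counts depended on single libraries. Without replicate 1 of met-2 the counts were 1762 higher and 198 lower, and leaving out any other library of these 2 mutants left 62 to 102 higher and 91 to 123 lower, with more lower than higher genes each time. With library medians set to 0 they were 143 higher and 272 lower.

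Dimethylated lysine 9 of histone H3 lies mostly on autosome arms in this species, so the positions of listed genes were compared with the annotation. Genes listed higher in met-2 lay on arms in 61.5% (889 of 1446 autosomal genes), against 61.9% of annotated autosomal protein-coding genes (Fisher exact test, adjusted p = 0.734). For lin-65 the share was 63.4% (adjusted p = 0.693). For the double mutant it was 58.0% (95% interval 55.7 to 60.2), below the annotation (Fisher exact test, adjusted p = 0.00128), and with genes within 20 kb counted once the share was 59.8% and no longer passed (p = 0.14). Genes listed in met-2 alone lay on arms in 76.2% (80 of 105, adjusted p = 0.00825), those in the double mutant alone in 52.6% (257 of 489, adjusted p = 1.42e-04). With neighbours within 20 kb counted once these were 73.7%, which no longer passed (Fisher exact test, adjusted p = 0.0678), and 54.1% (adjusted p = 0.00784). Genes listed lower in the double mutant lay on arms in 74.3% (78 of 105, Fisher exact test, adjusted p = 0.0258). The background counts all annotated protein-coding genes, including those without transcripts in embryos, so arm bias among expressed genes was not measured. The X chromosome held 407 of 1853 protein-coding higher genes in met-2, 18.6% in lin-65 and 22.5% in the double mutant, against 13.7% of protein-coding genes (adjusted p = 2.79e-24, 1.02e-04 and 4.13e-36).

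Pseudogenes were rare among genes listed higher. They made up 0.962% of annotated higher genes in met-2 (18 genes), 1.44% in lin-65 (12 genes) and 0.819% in the double mutant (20 genes), against 9.62% among annotated protein-coding genes and pseudogenes (adjusted p = 7.39e-60, 1.09e-22 and 9.41e-83). Among genes listed lower in lin-65 and the double mutant the shares were 8.18% (9 genes) and 6.56% (8 genes), which did not pass (Fisher exact test, adjusted p = 0.746 and 0.424). With a 4-fold limit the share of higher genes in lin-65 was 6.67% and did not pass (Fisher exact test, p = 0.798). The background counts all annotated genes, including those without transcripts in embryos.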

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

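All tests of explanations in this part, except that of embryo age within met-2 with genes as units, were chosen after the result was seen, and so was the limit of 95% for arms. By camera with preset correlation, 12 gene lists differed between lin-65 and met-2, none of them with an estimated correlation. Median differences (lin-65 minus met-2) were positive for oocyte and eggshell genes (1.17), meiosis (0.97), germ granule and germ cell genes (0.42) and Argonaute factors (0.20). They were negative for heat shock genes (−2.21), pharynx (−1.19), collagens (−1.07), intestine (−1.03), immune effectors (−0.89), C-type lectins (−0.73) and body wall muscle (−0.71). For chemoreceptors the median was −0.16, but camera placed them above the other listed genes (adjusted p = 0.0389), the median over all listed genes being −0.42. With library medians set to 0, the chemoreceptor difference became 0.22 and the others kept their sign.

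Genes of 6 tissue lists (283 genes) were listed higher for 107 in met-2, 16 in lin-65 and 122 in the double mutant. Older embryos alone are argued against for lin-65 by the over-representation of oocyte and eggshell genes (Fisher exact test, adjusted p = 8.75e-06), whose transcripts would fall with age. A lower age of the lin-65 embryos would instead raise these transcripts, and it was not tested. A single scaling factor as the whole cause would move all genes alike. In met-2 the tissue-list genes with values stood 1.39 above oocyte and eggshell genes (mean over 3 libraries, 95% interval 0.03 to 2.75). The lowest of 19 muscle genes (1.35) lay above the highest of 8 oocyte genes (0.59). The selection favours this gap, since 107 tissue-list genes were themselves selected as higher in met-2 and no oocyte gene was. The gap therefore cannot decide on a single factor. Over the whole lists, 19 of 22 muscle genes and 0 of 20 oocyte and eggshell genes were listed higher in met-2. A common shift as part of the cause was not tested. For derepression on arms as the source of the whole double mutant list, 58.0% of its autosomal higher genes lay on arms and 789 of 1877 did not. The limit of 95% was set with this share known, so falling under it is no test. The values show only that 789 of these genes lay off the arms. Derepression of a part of the list was not tested. For met-2, where library 1 stood above the others, tissue-list genes exceeded other listed genes of like mean by a further 0.059 in that library (permutation p = 0.0213 with genes as units), but with the 6 lists as units, 5 of them above 0, the mean of 0.078 did not pass (exact permutation p = 0.125), so embryo age stays open.

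Heat shock genes stood low in lin-65 and the double mutant. Stress in the N2 libraries alone is argued against, because it would lower all mutants alike, and the 9 genes differed between lin-65 and met-2 by a median of −2.34, each past limma's threshold. Handling that set the lin-65 and double mutant collections apart cannot be told apart from loss of LIN-65: both predict the same values, and the median difference of the double mutant from lin-65 was −0.43. Growth times differed by strain, no batch is labelled, and an effect of the genotype was not tested separately.

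Library 1 of met-2 stood above libraries 2 and 3. A single scaling factor is argued against, since its median shift was 0.58 for genes above 1.5 in the other libraries and −0.01 for genes below 0, a difference of 0.59 (bootstrap 95% interval 0.51 to 0.67). The shift was 0.45 for genes at 0.5 to 1 and 0.58 for genes above 1.5, a difference of 0.13 (0.09 to 0.16). It thus rose with the size of the change, but less than in proportion. Whether the same change was larger in that library stays open. Apart from embryo age, treated above, no other explanation was tested there.

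Other divisions of the 6 libraries of each pair of mutants were also fitted with limma, with these 2 mutants alone in the fit and genes of both directions counted. For the double mutant and met-2, 1 of 10 splits, the real one, gave as many genes: 348 against 0 in the highest other (375 at an unadjusted p under 0.05). For the double mutant and lin-65 it was 1 of 10, with 2510 against 0 (17 unadjusted), and for lin-65 and met-2 1 of 10, with 1084 against 0 (122 unadjusted). With 10 splits the share is never small enough for a test at 0.05.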

How the results depend on the processing

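Centring, library weights, fits of 2 mutants, single libraries left out of the limma fits, the limit met in every library, the background of listed genes, Spearman's rho and the treatment of genes lower than N2 were chosen after seeing the data. The tables allow no stricter adjusted p, other count normalization, DESeq2, count filter, pseudocount, expression filter or N2 library left out, so these were not run; the depth is unknown. Of the alternatives to the main comparisons 122 kept their value or call, 36 values moved, 3 were reversed, 1 passed the threshold and 2 no longer passed it. Kept means counts within 1.5 times, other values within 1 SD between libraries or their pairs, and tests on the same side of 0.05. The 2-fold limit repeats the authors' own selection, so its entries among the 122 could not change. For single named genes all 1215 means with 1 library left out stayed within 1 SD of the mutant's 3 libraries. Leaving out 1 of 3 libraries cannot move a mean by that SD, so this outcome was fixed in advance. At 4-fold the genes higher in met-2, lin-65 and the double mutant were 286, 48 and 639, and the lower ones 1, 17 and 19; lower genes past 2-fold in every library were 8, 67 and 73. Fewer genes follow from the stricter limits. Leaving out a library of the same mutant left 1597 to 1903, 760 to 839 and 2442 to 2456 higher genes. Against listed genes only, the overlap of lin-65 and the double mutant turned to 0.989 of expectation, and lists over-represented fell from 5, 2 and 6 to 1, 1 and 0. Of the 2828 genes in this background 2422 were themselves listed higher in the double mutant, so neither measure could rise far there. For met-2 (1853 genes) and lin-65 (823 genes) the share is lower, and the cause was not tested. Against all annotated genes the lists rose to 13, 6 and 13, with a background of 46926 instead of 19985 genes; the arm shares of met-2 and lin-65, 61.9% and 64.02%, then lay below a background of 71.7%. At 4-fold 0 lists passed in lin-65, and its pseudogene share was 6.67%. With neighbours counted once the arm share of the double mutant was 59.8%, past the threshold no longer; the cause was not tested. The lowest Spearman's rho within a mutant was 0.829 against Pearson's 0.882.

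With library medians set to 0 the differences over shared genes were 0.086 (lin-65 minus met-2), 0.066 (double mutant minus met-2) and 0.015 (double mutant minus lin-65), and genes higher and lower between mutants were 143 and 272 (double mutant against met-2), 637 and 486 (against lin-65) and 366 and 523 (lin-65 against met-2), against 348 and 145, 2190 and 136, and 145 and 1236. Centring on listed genes also removes a true general difference between mutants, so these changes do not show an effect of scaling. With library weights the double mutant against met-2 gave 1992 and 245, and in a fit of these 2 mutants 218 higher. Leaving out libraries gave 62 to 1762 higher and 91 to 198 lower genes there, both maxima without replicate 1 of met-2, and 780 (without lin-65 replicate 1) to 1427 lower genes for lin-65 against met-2. For these limma counts the cause was not tested. Replicate numbers did not pair the samples: correlations of same-numbered deviations ran from −0.21 to 0.04, with 0 of 9 above 0.1. With the replicate number as a block the counts were 248 and 134, 2124 and 109, and 133 and 1130.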

Other observations

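The family screen and the neighbour counts were chosen after the results were seen, and genes named here outside the naming rule after their values were seen. Gene families outside the fixed lists were screened by symbol prefix with Fisher exact tests over 240 prefixes. Several families were over-represented among genes listed higher. Of 10 warthog genes (wrt) 6 were listed in met-2 (adjusted p = 0.00286), 5 in lin-65 (adjusted p = 0.00595) and 6 in the double mutant (adjusted p = 0.0054), with wrt-1 at 2.52 ± 0.39, 2.18 ± 0.24 and 3.33 ± 0.05 (SD over 3 libraries). Of 24 patched-related genes (ptr) 15, 6 and 15 were listed (adjusted p = 1.42e-08, 0.0273 and 3.68e-07), with ptr-16 at 2.13 ± 0.57, 1.84 ± 0.27 and 3.07 ± 0.07. Ground-like genes (grl) gave 10 of 31 in met-2 (adjusted p = 0.00534) and 10 in the double mutant (adjusted p = 0.0207), where grl-5 stood at 3.15 ± 0.01. The cuticlin-like family (cutl) gave 10 of 29 in met-2 (adjusted p = 0.0047) and 12 in the double mutant (adjusted p = 0.0012). Genes with the prefix dyf were listed for 6 of 12 in met-2 (adjusted p = 0.00534) and 10 of 12 in the double mutant (adjusted p = 1.41e-06), with dyf-6 at 1.81 ± 0.41 and 2.31 ± 0.08. Where lin-65 is not named for a family, its members did not pass there.

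Some genes were highest in met-2 and not in the double mutant. The value of srw-85 was 4.54 in met-2, 0.27 in lin-65 and 0.74 in the double mutant, and the limma difference of the double mutant from met-2 was −3.81 (adjusted p = 9.92e-10). ZK1053.1 and ZK1053.2, which lie next to each other on chromosome I in WBcel235, stood at 2.66 and 3.25 in met-2, 0.80 and 1.46 in lin-65, and 0.88 and 1.20 in the double mutant; the double mutant differed from met-2 by −1.78 and −2.05 (adjusted p = 1.76e-06 and 2.09e-07). C55C3.3 stood at 4.11, 3.91 and 2.89, so that the double mutant lay below both single mutants (−1.21 and −1.02, adjusted p = 9.31e-05 and 1.18e-04). The F-box gene fbxa-107 stood at 0.23 in met-2, 1.70 in lin-65 and −0.57 in the double mutant, and Y37E11AL.1 at 1.05, 3.52 and 3.58.

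Within met-2, oocyte and eggshell genes had library medians of 0.09, 0.48 and 0.23, with the lowest in library 1, where tissue lists had their highest medians. Listed genes also had neighbours more often than random sets of protein-coding genes: 59.7% of higher genes in met-2 and 68.2% in the double mutant had another within 20 kb, against 54.7% and 64.1% on average and at most 58.9% and 67.2% in 1000 random draws. In lin-65 the share was 36.1%, against 30.04% on average and at most 38.5%.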
